A study of Mus musculus with 6 samples.

How the data were processed

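RNA of R1 mouse embryonic stem cells was measured on Affymetrix Mouse Genome 430 2.0 arrays, with 3 arrays of Sirt1+/+ cells and 3 of Sirt1-/- cells. The arrays were grouped by genotype as given in the labels. The deposited values were produced by the authors with RMA in Partek 6.5, per the submitters' processing notes. RMA corrects background, normalises arrays by quantiles and summarises the probes of a probe set by median polish. The deposited values are on a log2 scale, which was taken from their range, and they were used without recentring. The order of steps, settings and annotation used by the authors are not given in the sources used here. The number of arrays, 3 per group, limits the precision.

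The table held 45101 probe sets. The 64 control probe sets were left out of the gene comparison. Of the others, 34945 were annotated to 1 gene symbol, 932 to several and 9160 to none. Those with several or no symbols, 10092 in all, were not used for genes. Each of the 18194 genes was represented by its probe set with the highest mean over the 6 arrays, with no filter on dim probe sets. By Entrez identifier 18032 genes matched the reference annotation on GRCm38.p6, which gave chromosome and gene order, and 0 symbols needed an update. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed.

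Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the 2 groups, two-sided) with Benjamini-Hochberg adjustment over all genes at 0.05, which left 4 residual degrees of freedom per gene before moderation. A change of at least 2-fold required in addition an absolute log2 change of at least 1. Sirt1 was also tested with an exact two-sided permutation test. The 27 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over lists, and the genes of 20 chromosomes were tested likewise, adjusted over chromosomes. Changed members were counted over all genes tested and adjusted over the list alone. Lists of under 5 measured genes would not have been tested. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, without a comparison with other genes.

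The 27 lists, the tests, the naming rule and most other settings tried were chosen before the data were examined. The lists cover naive pluripotency, primed epiblast, retinoic acid signalling, Hox genes, neuroectoderm, mesoderm, endoderm, trophectoderm, germline, the 2-cell-like state, p53 targets, methionine and one-carbon metabolism, the Myc network, glycolysis, fatty acid oxidation, cholesterol synthesis, NF-kB, interferon response, imprinted genes, LIF, BMP and Wnt targets, sirtuins and NAD metabolism, DNA methylation and Polycomb, cell cycle, stress response, fibroblast markers, Y-linked genes and ribosomal proteins. The rule named Sirt1; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with no overlap between groups, with a brighter group mean above the median of all genes and a symbol that is not a predicted or clone name; up to 4 members of each list with the largest change past the threshold; Pou5f1, Nanog, Sox2, Crabp1, Crabp2, Rarb, Cyp26a1 and Hoxb1; and Y-linked genes. Another item of the rule is not reported here. Other genes named were chosen after their values were seen.

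The other settings chosen then were quantile normalisation repeated over all probe sets, arrays centred on their medians, removal of the dimmest 40% of genes, the mean of all probe sets of a gene, an intensity trend with a robust variance model, the replicate number as a block, each array left out in turn, an unmoderated linear model, unequal variances, an adjusted p under 0.01, limma's treat against a 1.5-fold change, all probe sets in place of genes, an estimated correlation and fry. Those added after the data were seen leave out the genes of chromosome 8, or rank genes in camera without the dimmest ones. Also added then were tests of gene families that share a symbol root and a scan along chromosomes. The scan took the running median of 21 neighbouring genes among 10879 expressed genes, with limits from 1000 permutations of gene order. The labels do not state whether like-numbered samples were handled together. The deviations of like-numbered arrays from their group means correlated across genes at 0.0515, -0.0864 and 0.198, where genes are not independent replicates. These low correlations do not exclude shared handling, since the poly-A and hybridisation controls rose with the replicate number in both genotypes.

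The procedure was tested on simulated data with 18194 genes. Of 50 genes changed by each size, 8% were recovered at a log2 change of 0.25, 78% at 0.5, 100% at 1 and 100% at 2, with 9 false calls. A list shifted by 0.3 was called, as were 0 of 26 other lists. The simulated genes varied independently and few of them were changed. The list result therefore does not show how often camera calls lists of correlated genes in data with many changes. The scan covered all 60 genes raised by 0.4 in 1 piece and called 0 pieces elsewhere among 9000 genes. These were real differences in random order. The scan's limits also come from random order, so the 0 pieces elsewhere say little about false stretches in real gene order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.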

Results

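Transcript levels were measured in R1 mouse embryonic stem cells, a line derived from 129-strain embryos, that carried either intact Sirt1 genes (Sirt1+/+) or none (Sirt1-/-). Sirt1 encodes an NAD-dependent protein deacetylase. Both kinds of cell were kept undifferentiated on gelatin in serum medium with leukaemia inhibitory factor (LIF), a cytokine that sustains self-renewal. Total RNA from 3 wild-type and 3 knockout samples was hybridised to 1 Affymetrix 3' expression array per sample, which gave log2 RMA levels for 45101 probe sets and 18194 named genes. The comparison asks which transcripts differ between cells with and without Sirt1. The labels name 1 knockout source and 1 wild-type source. For every result below, an effect of Sirt1 loss therefore cannot be told apart from other differences between the sources. The number of arrays, 3 per genotype, limits the precision of every value below. The labels do not state whether the 3 samples of a genotype came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

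The arrays were alike in overall level, with medians over all probe sets of 4.54, 4.57 and 4.53 in wild type and 4.56, 4.51 and 4.51 in knockout. Across the 18194 named genes, each read on its brightest probe set, Pearson's r was 0.997 to 0.998 between arrays of one genotype. It was 0.989 to 0.991 between genotypes, where genes are not independent replicates. The median within-group SD of a gene was 0.0985 log2 units. The 3' minus 5' difference of the Actb control probe sets, a sign of RNA integrity, was 0.98 ± 0.07 (SD, n = 3) in wild type and 0.90 ± 0.01 (SD, n = 3) in knockout. For Gapdh it was -0.04 ± 0.02 and -0.06 ± 0.02 (SD, n = 3 each). The poly-A RNA controls, added to the sample before labelling, read 7.62 ± 0.09 in wild type and 7.82 ± 0.13 in knockout (SD, n = 3 each), with overlapping arrays. The hybridisation controls read 9.55 and 9.57. Both kinds of control rose with the replicate number in each genotype. The poly-A controls read 7.55, 7.59 and 7.73 in wild type and 7.71, 7.78 and 7.97 in knockout. The hybridisation controls read 9.49, 9.51 and 9.65 in wild type and 9.49, 9.57 and 9.66 in knockout.

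Sirt1 RNA was lower in every knockout array. Its 1 named probe set (gene on chromosome 10) read 10.16 ± 0.06 in wild type and 8.05 ± 0.14 in knockout (SD, n = 3 each). The log2 change was -2.11 (SE 0.08), a 4.31-fold lower level (limma, Benjamini-Hochberg adjusted p = 3.98e-05). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. The position of this probe set relative to the deleted part of the gene is not given in the sources used here. The knockout level of 8.05 stayed above the median level of all named genes, 5.82.

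Of the 18194 named genes, 5462 (30.02%) differed between genotypes in limma at a Benjamini-Hochberg adjusted p under 0.05. In the knockout, 2270 of them were higher and 3192 lower. Most differences were small, with a median absolute log2 change of 0.39 among the changed genes. A change of at least 2-fold was seen for 352 genes, 92 higher and 260 lower, and one of at least 4-fold for 22 genes, 4 higher and 18 lower. The 3 knockout values lay wholly above or below the 3 wild-type values for 7973 genes (43.8%), against the 10% that chance gives. Genes of chromosome 8 made up 313 of the 2270 higher genes and 25 of the 92 that were at least 2-fold higher. With probe sets of a gene averaged in place of the brightest one, 226 genes changed at least 2-fold.

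The 12 largest rises were in genes of varied function. Nupr1, a stress-induced chromatin protein, rose from 8.64 ± 0.08 to 10.83 ± 0.06 (SD, n = 3 each), a log2 change of 2.20 (SE 0.06; limma, Benjamini-Hochberg adjusted p = 2.62e-05). Pla2g7, a phospholipase that inactivates platelet-activating factor, rose by 2.14. Rgcc, a regulator of the cell cycle, rose by 2.01, and Fam13c by 1.96. Cdkn2a, which encodes the cyclin-dependent kinase inhibitor Ink4a and the p53 activator Arf, rose from 5.17 ± 0.12 to 7.08 ± 0.12 (SD, n = 3 each), a log2 change of 1.91. P2rx3, an ATP-gated channel, rose by 1.77, the glutathione transferase Gstm2 by 1.75 and the G protein subunit Gna14 by 1.74. Dppa3, a maternal factor that guards DNA methylation in the early embryo, rose by 1.70. The remaining 3 of the 12 largest rises were genes of chromosome 8: Wwox (2.10), Nr2c2ap (1.73) and Apela (1.70), which encodes a secreted peptide ligand. In limma the Benjamini-Hochberg adjusted p of the 12 genes lay between 2.30e-05 for Rgcc and 0.00162 for P2rx3. For Wwox, Fam13c, P2rx3 and Nr2c2ap 1 probe set lay above the median level, and their other probe sets reached down to 0.09, 0.03, -0.04 and 0.07. Of these dimmer probe sets, some also rose: for Fam13c by 1.55 and 0.78, for P2rx3 by 1.12 and for Wwox by 0.72 and 0.46.

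The largest falls were in noncoding RNAs of imprinted regions. Meg3 (chromosome 12) fell from 10.83 ± 0.06 to 5.42 ± 0.12 (SD, n = 3 each), a log2 change of -5.41 (SE 0.07), or 42.4-fold lower (limma, Benjamini-Hochberg adjusted p = 1.94e-06). Rian, transcribed from the same imprinted domain, fell by 5.09, and Snhg14, the host of small nucleolar RNAs on chromosome 7, fell by 4.93. The Y-linked genes Uty and Uba1y fell by 4.22 and 2.12. The knockout means of Snhg14 (2.79) and Uty (2.88) lay below the lower quartile of every array (3.16 to 3.24), where background limits a measured fold. Stra8, induced by retinoic acid at the entry to meiosis, fell from 8.86 ± 0.12 to 5.88 ± 0.06 (SD, n = 3 each), or 7.89-fold. The serpin Serpinb6c fell by 2.40, the proteoglycan core protein Srgn by 2.38 and the growth factor Pdgfc by 2.37. The phospholipase Pla2g1b fell by 2.31, the endocytic receptor Cubn by 2.24 and the serine protease Tmprss13 by 2.17. In limma the Benjamini-Hochberg adjusted p of the 12 genes was at most 9.29e-05, the value for Serpinb6c.

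**Figure D1:**
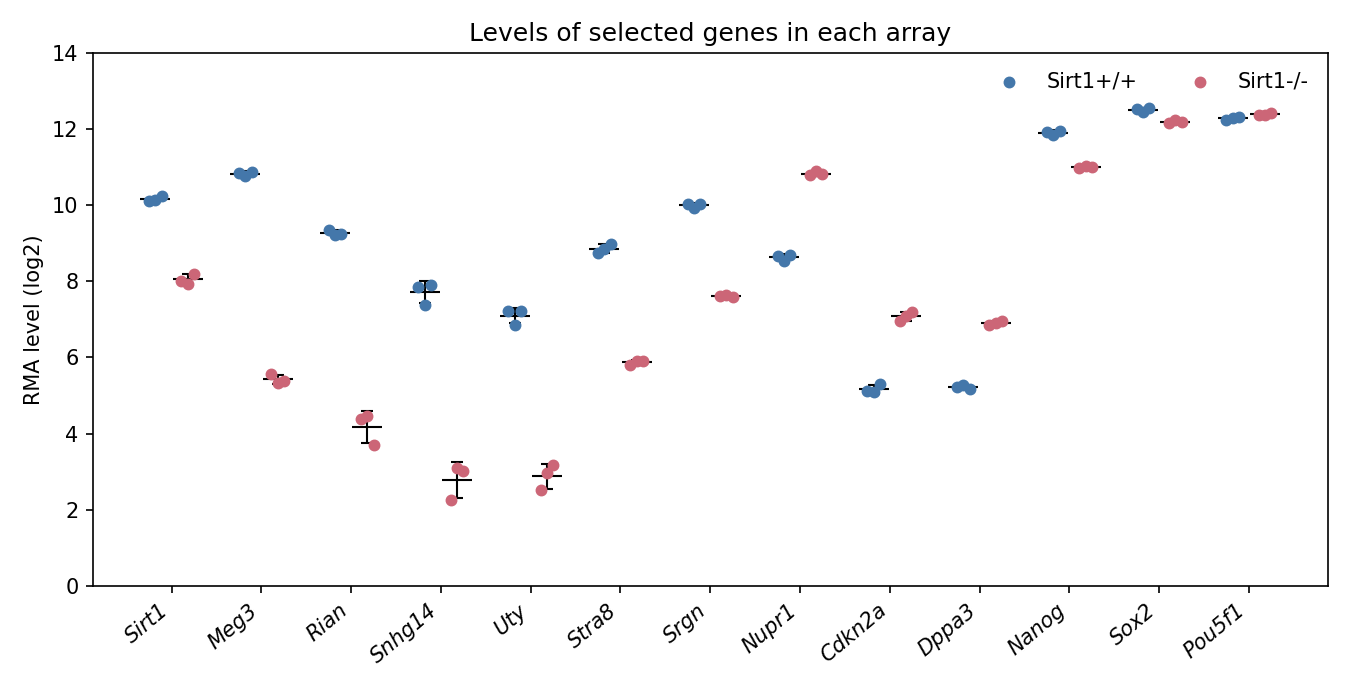
Levels of 13 genes in each array on the log2 RMA scale (vertical axis), with 3 wild-type arrays in blue and 3 knockout arrays in red; horizontal marks are means and bars are SDs. Sirt1 sat at 10.16 and 8.05, Meg3 at 10.83 and 5.42 and Cdkn2a at 5.17 and 7.08, while Pou5f1 read 12.29 and 12.39.

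Genes were then grouped into 27 lists fixed beforehand. For each list the members past the threshold over all genes tested are counted. The counts adjusted over the list alone are given where they differ.

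Naive pluripotency genes were lower as a group while Pou5f1, the central factor of the network, was not. Of 27 measured genes 2 rose, 16 fell and 9 did not pass (3 rose and 17 fell adjusted over the list alone). Nanog, at 11.91 ± 0.06 in wild type (SD, n = 3), fell by 0.90 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00010). The Krüppel-like factor Klf5 fell by 0.87, the chromatin regulator Prdm14 by 0.84 and Sox2 by 0.31. Pou5f1 read 12.29 ± 0.04 and 12.39 ± 0.02 (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.154). Dppa3 and Lin28a were the genes that rose. The median log2 change of the list was -0.23 (camera, adjusted p = 0.000785), with adjusted p = 0.157 with an estimated correlation. Of 16 primed epiblast genes 3 rose and 7 fell (4 rose adjusted over the list alone). Otx2 fell by 1.57 and Nodal by 0.73, whereas Zic5 rose by 1.11 and the DNA methyltransferase Dnmt3a by 0.79, with its probe sets down to -0.02 (camera, list adjusted p = 0.522). None of the 9 measured genes of the 2-cell-like state passed in limma, and 2 had an unadjusted p under 0.05 (camera, list adjusted p = 0.789).

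Genes of retinoic acid signalling moved in both directions. Of 36 measured genes 7 rose and 6 fell, and the list did not pass in camera (median log2 change 0.01, mean -0.03; adjusted p = 0.549). The median changed sign without wild-type replicate 3 (-0.0239) or knockout replicate 1 (-0.0174) and was highest without wild-type replicate 1 (0.0260). Crabp2, which carries retinoic acid to its nuclear receptors, rose by 1.31, from 5.26 ± 0.07 to 6.56 ± 0.23 (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.000471). Cdx1, a homeobox target of retinoic acid, rose by 0.99. Stra8 and the plasma retinol carrier Rbp4 fell by 2.98 and 1.10, and Crabp1 fell by 0.51. The log2 change was -0.49 for Rarb (limma, Benjamini-Hochberg adjusted p = 0.0784), -0.05 for Cyp26a1 (0.715) and 0.03 for Hoxb1 (0.881), none past the threshold. Of 33 Hox genes 2 rose and 1 fell (camera, list adjusted p = 0.367): Hoxb13 rose by 0.67, Hoxd9 by 0.30, and Hoxd1 fell by 1.04, with group means no higher than 4.81.

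Endoderm markers were lower as a group. Of 28 measured genes 14 fell, 15 adjusted over the list alone, and none rose in limma (1 at an unadjusted p under 0.05). Srgn fell by 2.38, Cubn by 2.24, and the endocytic adaptor Dab2 fell from 6.26 to 4.46. Col4a2, a chain of basement membrane collagen, fell from 8.07 ± 0.07 to 6.55 ± 0.03 (SD, n = 3 each), a log2 change of -1.52 (limma, Benjamini-Hochberg adjusted p = 3.69e-05). The list median was -0.31 (camera, adjusted p = 6.81e-07), with adjusted p = 0.0961 with an estimated correlation. Germline genes were lower too. Of 20 measured genes 1 rose and 12 fell, among them Stk31 (-1.29), Taf7l, Mael (-0.88), a factor of transposon silencing, and Hormad1 (-0.76). The median of the germline list was -0.28 (camera, adjusted p = 0.00510), with adjusted p = 0.475 with an estimated correlation.

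The other lineage lists were not shifted in camera, and fry called neuroectoderm lower (adjusted p = 0.0291). Of 22 neuroectoderm genes 3 rose and 6 fell (4 rose adjusted over the list alone; camera, list adjusted p = 0.808). Nefl fell by 0.84 and Tubb3 and Msi1 rose by 0.76 and 0.66. Ncam1 fell by 0.81 on its brightest probe set, while another of its probe sets was called in the opposite direction. The neuroectoderm median of 0.01 and mean of -0.06 differed in sign. Of 26 mesoderm genes only Pdgfra passed in limma, falling by 1.52, and 0 rose (1 at an unadjusted p under 0.05; camera, list adjusted p = 0.367; median 0.05, mean -0.00). The mesoderm median was 0.0272 without knockout replicate 1 and 0.0825 without knockout replicate 2. Of 18 trophectoderm genes 3 rose and 2 fell (camera, list adjusted p = 0.497). Gata2, also a blood and neural factor, rose by 1.20, Peg10 by 0.93 and Krt8 by 0.40, and Krt7 fell by 0.89. Fibroblast markers, which would report feeder cells, gave 2 higher and 3 lower of 22 (1 higher adjusted over the list alone; camera, list adjusted p = 0.789; median 0.00, mean -0.09). Thy1, Col5a1 and Pdgfrb fell by 1.07, 0.63 and 0.50, and Twist1 rose by 0.48. Another Col5a1 probe set above the median level read -0.44 and did not pass.

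The lists of cholesterol synthesis and of methionine and one-carbon metabolism were higher, and that of glycolysis lower. Of 24 genes of cholesterol synthesis and LXR targets 16 rose and 2 fell (17 rose adjusted over the list alone). Mvd and Cyp51, enzymes of sterol synthesis, rose by 1.03 and 0.90, the isoprenoid enzyme Fdps by 0.73 and the stearoyl-CoA desaturase Scd1 by 0.72. For Cyp51 the level went from 8.23 ± 0.06 to 9.13 ± 0.03 (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.000107). The list median was 0.39 (camera, adjusted p = 6.81e-07), with adjusted p = 0.197 with an estimated correlation. Mvd lies on chromosome 8. Of 24 genes of methionine and one-carbon metabolism 10 rose and 2 fell (4 fell adjusted over the list alone). Cth, which makes cysteine from cystathionine, rose from 10.63 ± 0.01 to 11.66 ± 0.05 (SD, n = 3 each), a log2 change of 1.04 (limma, Benjamini-Hochberg adjusted p = 6.23e-05). Spermidine synthase Srm rose by 0.84, the mitochondrial folate enzyme Mthfd2 by 0.74 and the serine synthesis enzyme Psat1 by 0.71. The median was 0.07 (camera, adjusted p = 0.0316), with adjusted p = 0.383 with an estimated correlation. Without wild-type replicate 2 the median was 0.04 and the call was lost (camera, adjusted p = 0.0658).

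Of 20 glycolysis genes 2 rose and 9 fell (11 fell adjusted over the list alone). The glucose transporter Slc2a1 fell from 13.10 ± 0.01 to 12.35 ± 0.09 (SD, n = 3 each), a log2 change of -0.75 (limma, Benjamini-Hochberg adjusted p = 0.000255). The lactate transporter Slc16a3 fell by 0.63 and hexokinase Hk2 by 0.62, while Eno2 rose by 0.67. The median was -0.15 (camera, adjusted p = 0.0213), with adjusted p = 0.475 with an estimated correlation. The glycolysis call was lost without knockout replicate 1 (median -0.14; camera, adjusted p = 0.0615) and without the dimmest 40% of genes (adjusted p = 0.0660). Of 24 genes of fatty acid oxidation and PPAR or PGC-1 targets 9 rose and 6 fell (10 and 7 adjusted over the list alone; camera, list adjusted p = 0.280). The fatty acid carrier Fabp3 and the thioesterases Acot1 and Acot2 rose by 0.86, 0.68 and 0.60, and Angptl4 fell by 0.65. Of 22 genes of the other sirtuins and NAD metabolism 4 rose and 3 fell (camera, list adjusted p = 0.367). Sirt3 rose by 0.26, and Parp2 fell by 0.25. Qprt fell by 0.36 on its brightest probe set and by 0.73 on another. Nampt rose by 0.24 on its brightest probe set, while its other probe sets read -0.17 and -0.05 and did not pass.

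The list of heat shock, unfolded protein and integrated stress response genes was higher as a group, with members that changed both ways. Of its 24 genes 13 rose and 5 fell (14 and 6 adjusted over the list alone). Herpud1 rose by 1.52, the lipoprotein receptor Vldlr by 1.42 and the transcription factor Ddit3 from 7.99 ± 0.06 to 9.26 ± 0.06 (SD, n = 3 each), a log2 change of 1.27 (limma, Benjamini-Hochberg adjusted p = 5.24e-05). Trib3, a target of Ddit3, rose by 0.96. The genes that fell were Hspa1b, Hspb1, Hsph1, Xbp1 and Hsp90aa1. The list median was 0.19 (camera, adjusted p = 0.0193), with adjusted p = 0.475 with an estimated correlation. Herpud1 lies on chromosome 8, and without the genes of that chromosome the call was lost (median 0.17; camera, adjusted p = 0.0534).

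Of 28 p53 targets 10 rose and 4 fell (6 fell adjusted over the list alone; camera, list adjusted p = 0.301). The death receptor Tnfrsf10b rose by 1.32 and Btg2 by 0.55, while Dram1 and Ckap2 fell by 1.08 and 0.45. Of 31 cell cycle genes 5 rose and 11 fell (6 and 13 adjusted over the list alone; camera, list adjusted p = 0.367). Beside Cdkn2a, Cdc25a rose by 0.43, and the cyclins Ccnd1 and Ccne2 fell by 0.71 and 0.50. Of 28 genes of the Myc network and ribosome biogenesis 9 rose and 2 fell (3 fell adjusted over the list alone; camera, list adjusted p = 0.154). The nucleolar GTPase Gnl3 rose by 0.52, Odc1 by 0.49 and Cad by 0.40, and Polr1b fell by 0.62. Another Odc1 probe set, also above the median level, read 0.07 and did not pass. Of 27 ribosomal protein genes 2 rose, Rpl14 by 1.60 and Rps6 by 0.56, and none fell in limma, nor at an unadjusted p under 0.05 (camera, list adjusted p = 0.273).

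None of the lists of signalling targets, inflammatory and interferon response, and DNA methylation and Polycomb machinery was shifted in camera. Of 29 LIF, BMP and Wnt targets 8 rose and 8 fell (11 and 11 adjusted over the list alone; camera, list adjusted p = 0.794; median -0.00, mean 0.02). The ETS factor Etv4 rose by 1.13, the ERK phosphatase Dusp6 by 0.99, and Id2, a BMP target, fell by 1.44 (limma, Benjamini-Hochberg adjusted p = 0.000144). The list is mixed: it also holds genes of ERK signalling such as Dusp6. Its counts therefore do not describe LIF, BMP and Wnt targets alone. Of 25 NF-kB and inflammatory genes 1 rose and 8 fell (camera, list adjusted p = 0.311), with Nfkbie at -1.15, Ier3 at -1.06, Birc3 at -0.84 and Tnfaip3 at -0.56. Nfkbie and Tnfaip3 had no probe set above the median level of named genes. Of 23 interferon response genes 5 rose and 2 fell (camera, list adjusted p = 0.217). Ifitm3 rose by 0.55, Bst2 and Ifih1 by 0.47 each, and the immunoproteasome subunit Psmb9 fell by 0.90. Ifih1 was dim, at 3.01 in wild type and 3.47 in knockout. Of 27 genes of the DNA methylation and Polycomb machinery 5 rose and 6 fell (7 fell adjusted over the list alone; camera, list adjusted p = 0.789). Bmi1 rose by 0.70, and Cbx7 and Mtf2 fell by 0.62 and 0.47.

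Imprinted genes changed in both directions. Of 33 measured genes 7 rose and 12 fell (13 fell adjusted over the list alone), with a median of -0.10 (camera, list adjusted p = 0.367). The noncoding RNAs Meg3, Rian and Mirg of one domain on chromosome 12 changed by -5.41, -5.09 and -2.11. All 9 of their 17 probe sets that lay above the median level in either genotype fell. Those of Meg3 and Mirg lay above it only in wild type, which fixes their direction. Kcnq1ot1, a noncoding RNA of chromosome 7, fell by 1.42 on its brightest probe set. Its 6 probe sets ranged from -2.08 to -0.04, and none lay above the median level. Peg10 rose by 0.93. Of 6 Y-linked genes 2 fell and 0 rose in limma, 0 also at an unadjusted p under 0.05 (camera, list adjusted p = 0.367). Eif2s3y stayed high, at 9.54 ± 0.02 in wild type and 9.13 ± 0.04 in knockout (SD, n = 3 each), a log2 change of -0.41 (limma, Benjamini-Hochberg adjusted p = 0.00102). Uty fell by 4.22, and the changes of Kdm5d, Usp9y, Zfy2 and Sry were 0.11, -0.24, 0.17 and 0.02 with no mean above 5.06, none past the threshold.

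**Figure D2:**
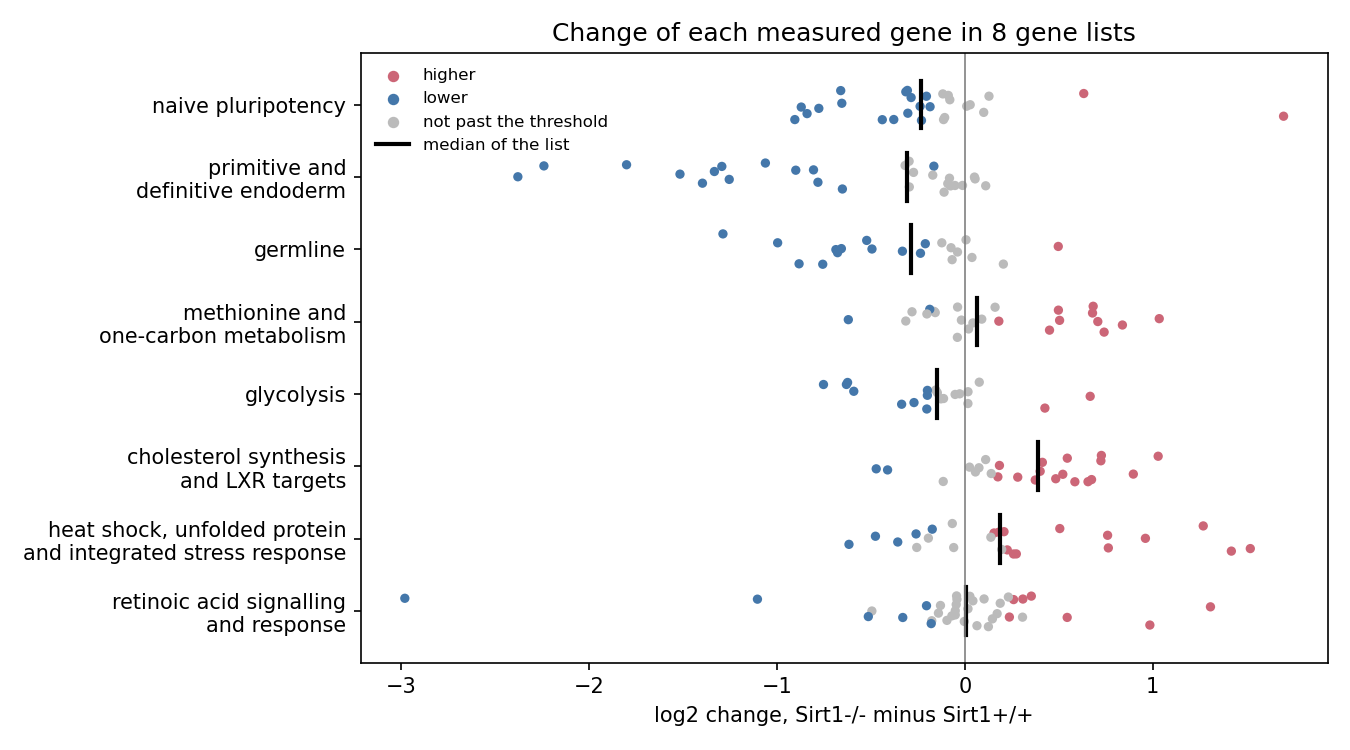
Log2 change, knockout minus wild type (horizontal axis), of each measured gene in the 7 lists with a shift in camera and in the retinoic acid list; each point is a gene, red where higher, blue where lower and grey where the adjusted p was not under 0.05, and black bars are list medians. The medians run from -0.31 for endoderm to 0.39 for cholesterol synthesis, and that of the retinoic acid list was 0.01, a value whose sign changed when single arrays were left out.

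Genes that complete the counts of 5 or fewer were named after their values were seen. The pluripotency factor Lin28a, the keratin Krt18, Nes, Dpep3, Pfkm, Ccl5, Ddx58, Ifit2, Sirt2, Ahcyl1, Cbx8, Pcgf1, Dnmt3l, Aurkb, Mcm5, Ccnd3 and Fn1 rose. Ets2, Ccng1, Rrm2b, Mthfd1, Gldc, Gart, the LXR targets Abca1 and Mylip, B2m, Nmnat3 and the 5 lower stress genes fell.

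In all, 7 of the 27 lists were shifted in camera with a preset correlation of 0.01 between genes, 3 up and 4 down. With a correlation estimated for each list, 0 of 27 passed in camera, 3 had an unadjusted p under 0.05, and fry called 18.

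Taken over whole chromosomes, genes of chromosome 8 were higher as a group, unlike those of any other chromosome tested. Of its 932 measured genes 313 (33.6%) rose and 98 fell, with a median log2 change of 0.08 (camera, adjusted p = 4.61e-06; adjusted p = 0.0178 with an estimated correlation). On the other 19 chromosomes 7.41% to 13.8% of genes rose, medians ran from -0.03 to -0.01, and the lowest adjusted p in camera was 0.923. Among the 603 expressed genes of chromosome 8, those left after removal of the dimmest 40% of genes, 66.8% were higher in knockout, against 39.0% to 47.9% on the other chromosomes. The rise covered the distal part of the chromosome. At every expressed gene before the 146th the running median of 21 genes lay below 0, down to -0.34. That did not pass the scan's lower limit of -0.44. In gene order on GRCm38.p6 the running median of 21 genes lay above 0 from Ufsp2, the 146th expressed gene, and the stretches past the scan's limit ran, with gaps, from Cpe, the 178th, to Gnpat, the 590th. Wwox, Nr2c2ap, Apela, Herpud1, Mvd and Tubb3 lie in this part, as does Klf2, which was chosen after its values were seen and fell by 0.78. Regional shifts were not particular to chromosome 8. The scan also found raised stretches on distal chromosome 9 (48 expressed genes, median 0.36) and on chromosome 15 (33 genes, median 0.31). A stretch on chromosome 14 was lower (22 genes, median -0.44).

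**Figure D3:**
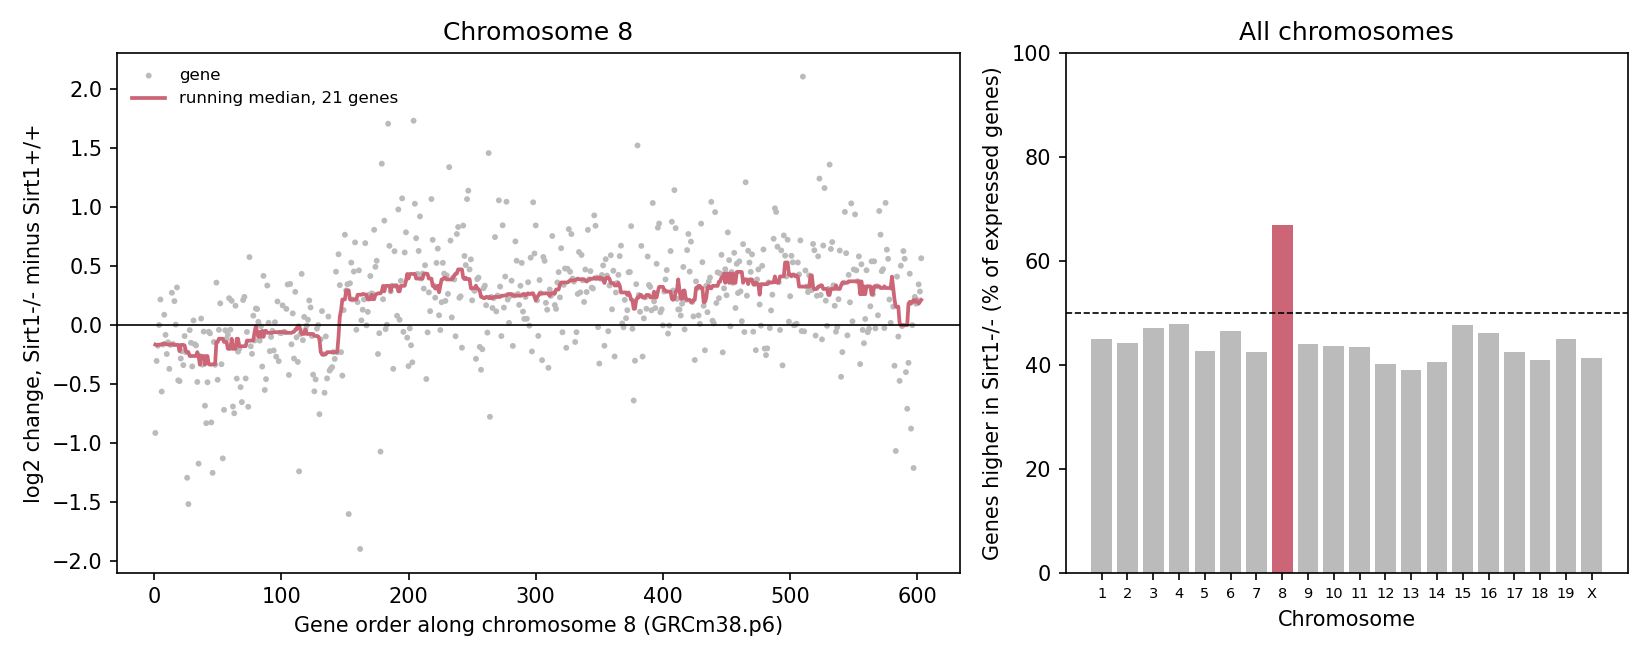
Left, log2 change, knockout minus wild type (vertical axis), of the 603 expressed genes of chromosome 8 in gene order (horizontal axis), each point a gene, with a running median over 21 genes in red; right, the percentage of expressed genes higher in knockout on each chromosome, with chromosome 8 in red and a dashed line at an even split. The running median lies below 0 before the 146th gene. From there to the end it lies above 0 except at the 587th to 592nd, where it is -0.00. Chromosome 8 stands at 66.8% while the others lie between 39.0% and 47.9%.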

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

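Probe sets without a single gene name were outside the gene comparisons, and a signal appeared among them. Of 10092 such probe sets, 946 (9.37%) differed between genotypes in limma with Benjamini-Hochberg adjustment, 515 higher and 431 lower in the knockout. Of these, 23 were at least 2-fold higher in the knockout arrays than in the wild-type arrays and 51 at least 2-fold lower. The largest rise was 2.53 and the largest fall -5.65 in log2. The share of 9.37% was below the 30.02% of named genes, each read on its brightest probe set. These shares are not strictly alike. The probe sets were adjusted over all non-control probe sets and the genes over the 18194 genes. Of the 10092 probe sets, 932 are annotated to several gene symbols. What the 9160 without a symbol detect is not given in the sources used here. No biological explanation was tested.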

How the results depend on the processing

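The settings without genes of chromosome 8 and with genes ranked without the dimmest ones were chosen after the data were seen. The 5462 changed genes became 3456 with unequal variances (1473 higher, 1983 lower), 3356 at an adjusted p under 0.01 (1347 higher, 2009 lower) and 8912 over all probe sets (4261 higher). The other settings gave 4104 to 6448, the lowest of them without wild-type replicate 1. The stricter threshold and the larger number of features account for 2 of these shifts by construction. Unequal variances found fewer of the simulated changes, 12% at a log2 change of 1 and 68% at 2. Limma found 100% of each. Whether this loss of power accounts for the whole shift in the real data was not tested. With the replicate number as a block, 4471 of the 5462 genes were called among 4700.

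The 352 genes changed at least 2-fold became 226 with the mean of all probe sets, 161 of them lower, and 642 over all probe sets, 220 higher and 422 lower. Leaving out 1 array gave 342 to 368. The mean dilutes a bright probe set with dim ones. Without genes of chromosome 8, 316 remained to be counted. Sirt1 stayed lower past the threshold under every setting run, with a log2 change of -2.18 to -2.05 when 1 array was left out. Chromosome 8 stayed the only chromosome called when 1 array was left out, at medians of 0.07 to 0.11.

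Of 27 lists 7 were called, against 0 with an estimated correlation, 18 with fry and 4 with ranked genes, and the cause was not tested. With an estimated correlation the medians stayed at -0.23 for naive pluripotency (adjusted p = 0.157), -0.31 for endoderm (0.0961), -0.28 for germline (0.475), 0.0669 for methionine metabolism (0.383), -0.15 for glycolysis (0.475), 0.39 for cholesterol synthesis (0.197) and 0.19 for stress response (0.475). Fry also called primed epiblast (median -0.252), neuroectoderm (0.0128), p53 targets (0.0117), the Myc network (0.0443), fatty acid oxidation (0.0861), NF-kB (-0.0507), interferon response (0.0869), imprinted (-0.103), cell cycle (-0.0890), Y-linked (-0.112) and ribosomal genes (0.00747). Neuroectoderm was called lower by fry despite its positive median. Some of these medians moved by more than 1.5 times when 1 array was left out: primed epiblast to -0.152, the Myc network to 0.01 and NF-kB to -0.00653 without wild-type replicate 2, NF-kB to -0.0774 without wild-type replicate 1, and the Myc network to 0.0265 and fatty acid oxidation to 0.0474 without knockout replicate 2. Leaving out single arrays also gave -0.0256 to 0.0367 for neuroectoderm, which changed sign without wild-type replicate 1 or 3 or knockout replicate 1, and 0.0156 to 0.0339 for p53 targets, -0.20 to -0.06 for Y-linked and 0.0103 to 0.0147 for ribosomal genes. Among lists called by neither test the ranges were 0.00390 to 0.0739 for Hox genes, 0.0153 to 0.129 for trophectoderm, -0.140 to -0.0111 for the 2-cell-like state, -0.0624 to 0.0202 for LIF, BMP and Wnt targets, 0.0101 to 0.107 for NAD metabolism, -0.0370 to -0.00992 for Polycomb and -0.0538 to -0.00955 for fibroblast markers. The mean of probe sets also called the Myc network (0.106). Methionine metabolism ranged from 0.0385 to 0.103 when 1 array was left out, the highest without wild-type replicate 3. It lost its call without wild-type replicate 2 (adjusted p = 0.0658). With genes ranked without the dimmest ones it stood at 0.14 (0.0652), the median of the members that remained. Glycolysis ranged from -0.17 to -0.14 and lost its call without knockout replicate 1 (adjusted p = 0.0615). It stood at -0.15 without the dimmest genes (0.0660), and also with genes ranked without the dimmest ones (0.0652). Stress response stood at 0.17 without genes of chromosome 8 (0.0534) and 0.19 with genes ranked without the dimmest ones (0.0856). Why these calls ended: the cause was not tested.

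Of the 120 genes named by rule, 18 lost their call with unequal variances, 9 at an adjusted p under 0.01, 8 in the unmoderated model, 5 with the mean of probe sets and 3 with the block, and 0 changed direction. The scalings left the median change of all genes between -0.01 and 0.00. Signal near background limits the folds of dim genes. Dram1, Hormad1, Rbp4, Slc16a3 and Peg10 are among the named genes with no probe set above the median level.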

Other observations

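The tests of gene families, the scan along chromosomes, the tests of an extra copy, another strain and loss of Sirt1, the tests of Meg3, Rian and Mirg, and the test of fewer endoderm-like cells were chosen only after the results they bear on were seen.

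Among 296 gene families defined by a shared symbol root, 3 were shifted in camera, and 0 with an estimated correlation (adjusted p = 0.980 for each; 8 families had an unadjusted p under 0.05). The genes named here were chosen after their values were seen. Ift genes, which encode proteins of intraflagellar transport in cilia, were lower, with 7 of 14 past the threshold and 0 higher (median -0.23; camera, adjusted p = 0.0161). Ift74 fell by 0.99, Ift81 by 0.80 and Ift140 by 0.79. Krüppel-like factors were lower, with 11 of 16 down and 2 up (median -0.45; camera, adjusted p = 0.0230). Klf12 fell by 1.03 and Klf9 by 0.74, while Klf15 and Klf16 rose by 0.71 and 0.66. Fkbp genes, which encode peptidyl-prolyl isomerases, were higher, with 7 of 12 up and 0 down (median 0.19; camera, adjusted p = 0.0369). Fkbp7 rose by 0.90 and Fkbp8, on chromosome 8, by 0.72.

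Of the imprinted genes, 6 neighbours in the Prader-Willi region of chromosome 7 fell; they were chosen after their values were seen, and no set test was run on them. Snhg14, Snrpn, Ndn, Magel2, Mkrn3 and Peg12 fell by 4.93, 0.72, 1.12, 0.39, 1.37 and 0.34, of which Magel2 and Peg12 were dim, at 3.53 and 2.98 in wild type. Ube3a, beside them, did not pass (log2 change 0.05; limma, Benjamini-Hochberg adjusted p = 0.488). On chromosome 6 the imprinted neighbours Sgce and Peg10 rose by 1.22 and 0.93.

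The scan along chromosomes found 8 segments, 5 of them on chromosome 8. On distal chromosome 9 the 48 expressed genes from Vill to Ppp2r3d had a median of 0.36, with 28 higher and 4 lower, and Rpl14 lies among them. On chromosome 15 the 33 from Acvr1b to Hoxc9 had a median of 0.31, and on chromosome 14 the 22 from Naa16 to Spry2 had one of -0.44. Causes were not tested for the stretches outside chromosome 8.

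Genes of distal chromosome 8 were higher in the knockout. A brightness or normalisation trend is argued against, since the highest median of 1000 random sets matched on level was 0.0184. A candidate explanation is an extra copy of part of the chromosome in the knockout cells: with the segment placed on replicate 1 of each genotype, 80.3% of its 402 expressed genes lay above 0 in the other 4 arrays, at a median of 0.33 (0.58 for 3 copies against 2), and the 188 genes before it, which include the raised genes from the 146th on, had a median of -0.07. The other 4 arrays come from the same cell sources, so these values show that the rise repeats and cannot single out an extra copy. A segment of another mouse strain stays open: at most 9.96% (upper 95% bound, genes taken as independent) of its changed genes were lower, but the segment was chosen for its rise, and probes that match 1 strain better could shift signals one way. Loss of Sirt1 itself cannot be told apart, because the labels name 1 knockout source.

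Meg3, Rian and Mirg were lower in the knockout. For faulty or cross-hybridising probe sets the count cannot decide. Of those above the median level in either genotype 9 of the 9 fell. Those of Meg3 and Mirg and the brightest of Rian lay above that level only in wild type. A probe set that passes in this way can only read lower in knockout. The values show that the fall of Meg3 was not confined to 1 probe set, with log2 changes from -5.99 to -3.68 among these. Among dimmer probe sets, those of Meg3 with log2 changes of -0.07, -0.21, -0.25 and -0.34 did not pass in limma. Loss of a wider chromosome region is argued against by the 20 neighbouring expressed genes, whose median was -0.0361. Loss of Sirt1 itself may underlie the fall, but it cannot be told apart from a difference between the lines, because the labels name 1 knockout source.

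Endoderm markers were lower in the knockout. A trend of genes at that level is argued against, since 0 of 1000 random lists matched on level had a median as low, and the lowest was -0.23. Fewer endoderm-like cells in the knockout cultures may explain the fall, but the counts cannot test it. Of 13 members above the median level in wild type 11 fell and 0 were higher. No member of the whole list had risen, so that 0 was known before the test was chosen. Fewer such cells cannot be told apart from lower expression in each cell, since the arrays average over cells.

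The 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.1. Every split but the real one mixes the genotypes in both groups, so the genotype difference widens its spread within groups. The low counts of such splits therefore do not measure what chance gives. The real split gave 5462 changed genes and the highest of the others 0, and 1 of 10 splits gave as many. For genes changed at least 2-fold the values were 352 and 0, with 1 of 10 as many. For lists they were 7 and 2, with 1 of 10 as many, and for chromosomes 1 and 1, with 2 of 10 as many.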
